A study of Rattus norvegicus with 20 samples.

How the data were processed

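RNA from the right ventricle of rats was measured on 20 Affymetrix expression arrays, 1 per tissue sample. Per the labels, male Sprague Dawley rats of about 350 g received polystyrene microspheres of 25 micron into the right jugular vein, suspended in 0.01% Tween-20, which lodge in the lung circulation and model chronic pulmonary embolism (PE). Control rats received 0.01% Tween-20 alone (vehicle). The hearts were taken 6 weeks later, and the right ventricle was divided into the outflow tract (base) and the apex. The 4 groups (vehicle apex, PE apex, vehicle outflow and PE outflow) held 5 arrays each, and 5 microgram of total RNA per sample went into biotin-labelled cRNA. A text field on animal treatment described the vehicle injection for all 20 samples, whereas the titles and the treatment field separate PE from vehicle, and the groups follow these. The sample fields give an injected volume of 0.15 ml per 100 g, while the text on the study design gives 0.01 ml for the vehicle.

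The deposited values are linear signal intensities, 1 per probe set (a set of probes for 1 transcript) and array, per the labels on the value column. The software and its settings are not given in the sources used here. After leaving out 2% of the values at either end, the mean signal of every array was 500.2, so the authors had scaled the arrays to a common level. The table held 31099 probe sets. The 57 control probe sets were used to describe the arrays and, through the GAPDH ratio, in some alternatives, and the 31042 others were tested. The platform annotation gave 1 gene symbol for 20826 of them, several for 436 and none for 9780, and 20758 were matched by Entrez gene identifier to a current rat gene table, which updated 0 symbols. Each of 14217 genes was represented by its probe set with the highest mean.

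Signals were transformed to log2 after adding 16. A linear model of the 4 groups was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3, with moderated variances (eBayes), and p-values were two-sided and adjusted by the Benjamini-Hochberg method over the 31042 probe sets. A change was called at an adjusted p under 0.05. The 5 comparisons were PE against vehicle in the apex, PE against vehicle in the outflow tract, the difference between these PE effects, and outflow against apex in vehicle rats and in PE rats. Fold changes are those of the signal plus 16. They carry the standard error (SE) of the model, and mean signals carry the standard deviation (SD) over 5 arrays. The number of arrays limits the precision.

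The groups, the comparisons, the tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. By that rule, the text names up to 12 genes with the largest rise and 12 with the largest fall among the called genes of a comparison (6 and 6 for the difference between regions), up to 4 members with the smallest p of a described list, and 20 index genes of load, matrix, inflammation and metabolism in each PE comparison. Genes outside the rule are named as such.

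The 36 gene lists held 931 members, of which 837 were measured. They cover the stretch and fetal programme, contraction and calcium handling, ion channels, extracellular matrix, proteases, TGF-beta and Wnt signalling, chemokines, complement, antigen presentation, interferon, energy metabolism, hypoxia, receptors, oxidative stress, immediate early genes, heat shock, the circadian clock, cell cycle, outflow tract regulators and markers of 15 cell types. Each list was tested with camera (limma) against all other genes with a preset correlation of 0.01 between genes, and adjusted over the 36 lists. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way without comparing them with other genes, were run beside it. With the estimated correlation no list was called in any comparison, against 10 in the apex, 17 in the outflow tract, 14 for the difference and 15 between the regions of PE rats with the preset one. Fry called 3, 26, 21 and 23 lists in these comparisons, and 0 between the regions of vehicle rats. Counts of members are given over all probe sets tested and adjusted over the list alone.

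Deviations from the group means over 12310 probe sets with a mean log2 signal above 8 were correlated between arrays. Arrays with the same replicate number in the apex and outflow groups of a treatment correlated at 0.181 to 0.283 in PE rats and at 0.181 to 0.276 in vehicle rats, and each of these arrays matched its own number best, so the replicate numbers were read as rats within a treatment. They did not pair vehicle with PE rats. The consensus correlation of such pairs was 0.0651, and a block for the rat was run as an alternative.

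The alternatives were quantile normalization, centring each array on its median, leaving out the 40% dimmest probe sets, adding 1 or 64 instead of 16, fitting only the compared groups, an intensity trend with robust variances, array weights, a fold of at least 1.5 as well, an adjusted p under 0.01, the replicate block, other probe sets of the named genes and leaving out each array in turn. After the data were seen, 3 more were added: leaving out PE outflow replicate 2 in every comparison, the GAPDH 3' to 5' signal ratio as a covariate, and keeping only PE outflow replicates 1 and 3, whose ratio lay under 2. The procedure was tested on simulated data with 200 changed probe sets of 31042 in each of 10 simulations. The changed ones were drawn outside the 40% dimmest and changed 1.5-, 2- or 4-fold in about equal numbers. With 1 spread for all groups, probe sets changed 2-fold were called in 74.8% of cases in the apex, 70.7% in the outflow tract, 41.9% for the difference, 71.3% between the regions of vehicle rats and 75.8% between those of PE rats. Unchanged probe sets made up 4.48% to 5.93% of the calls. With each group's own spread, their share was 12.7% in the apex, 31.8% in the outflow tract, 9.54% for the difference and 29.6% between the regions of PE rats. Probe sets with several gene symbols or none entered the counts of probe sets but not those of genes. No value column of the table was left out.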

Results

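Signals of 31042 probe sets were compared between 20 arrays of rat right ventricle, 5 in each of 4 groups: the apex and the outflow tract of vehicle rats and of rats with 6 weeks of chronic PE. The median signal of an array lay between 123.02 and 159.4. Arrays correlated with the others of their group at a mean r of 0.962 to 0.971 in the vehicle groups and the PE apex group, and at 0.929 to 0.963 in the PE outflow group. The ratio of 3' to 5' signal of the GAPDH control probe sets, which rises when RNA or its labelled copies are short, was 1.38 to 1.83 on the 10 vehicle arrays and 1.47 to 1.67 on the PE apex arrays. In the PE outflow group it was 6.12 on the array of replicate 2, 2.20 on replicate 4 and 2.34 on replicate 5, against 1.70 and 1.71 on the other arrays. The beta-actin ratio was 11.5 on replicate 2, 4.0 on replicate 4 and 4.54 on replicate 5, against up to 3.14 on the vehicle arrays.

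**Figure D1:**
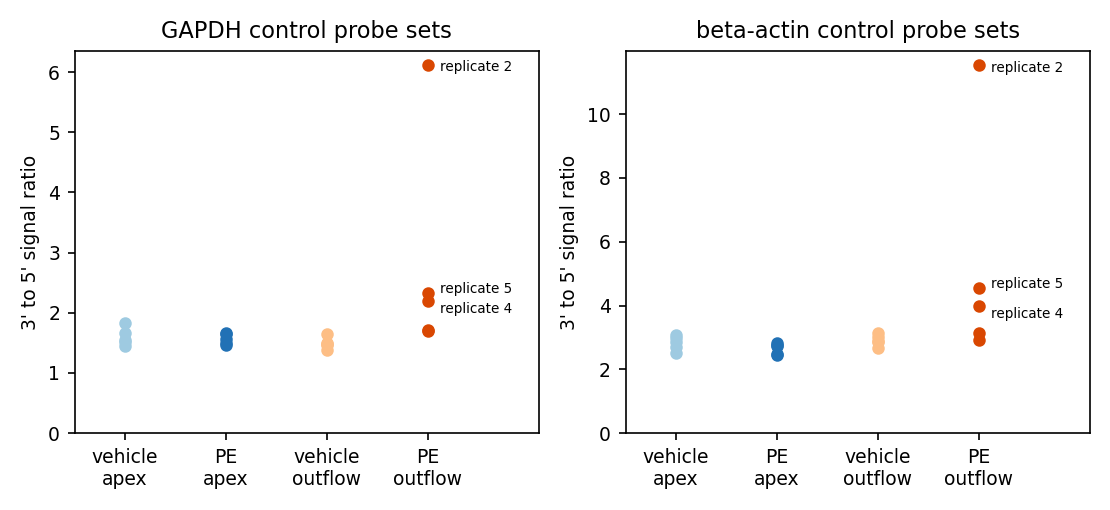
Ratio of 3' to 5' signal of the GAPDH and beta-actin control probe sets on each array, by group, with 1 point per array. The PE outflow arrays of replicates 2, 4 and 5 lie above every vehicle array for both controls, with replicate 2 at 6.12 and 11.5.

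The first comparison asked what the apex of the right ventricle expressed differently after PE. Nppa, which encodes atrial natriuretic peptide, a hormone of stretched heart muscle, rose 13.8-fold (log2 3.78 ± 0.48, SE, n = 5 per group, limma adjusted p = 0.00591), from a mean signal of 881 ± 448 (SD) to 13880 ± 8262. Sbsn, which encodes suprabasin, a protein best known from the epidermis, rose 3.85-fold (log2 1.95 ± 0.29, adjusted p = 0.0212), from 228 ± 43.2 to 949 ± 336. Mfap4, an extracellular protein associated with elastic fibres, rose 2.12-fold (log2 1.09 ± 0.17, adjusted p = 0.0212), from 3136 ± 467 to 6742 ± 1339. For these 3 genes all 5 PE arrays lay above all 5 vehicle arrays, but Sbsn and Mfap4 lost their calls in many settings, as given below. A dim probe set without a gene symbol rose 2.72-fold (log2 1.44 ± 0.20, adjusted p = 0.0156), from 9.93 ± 9.48 to 51.2 ± 1.92, and is outside the naming rule, chosen after its values were seen. In all, 4 of 31042 probe sets rose and 0 fell by limma in the apex, with 2320 (7.47%) at an unadjusted p under 0.05.

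The other index genes did not pass the test in the apex. Among markers of load, Nppb (brain natriuretic peptide) had a log2 fold change of 1.18 ± 0.26 (adjusted p = 0.16), while Myh6 and Myh7, the fast and slow cardiac myosins, had -0.20 and 0.03. For Nppb and Tgfb2 all 5 PE apex arrays lay above all vehicle apex arrays. In the outflow tract Nppb was called at a smaller 0.99 ± 0.26. The adjustment is stricter in the apex, where few probe sets had a small p, so the calls of Nppb do not show a regional difference. Acta1 had 0.22, Ankrd1 -0.08 and the calcium pump gene Atp2a2 -0.17. Under quantile normalization, Ankrd1 and Atp2a2 had the opposite sign (0.09 and 0.03). No other probe set of the index genes was called in the apex, where a dimmer one of Myh7 had 0.67 and one of Col1a1 0.22. Matrix genes had 0.62 ± 0.18 (Col1a1, adjusted p = 0.346), 0.39 ± 0.12 (Col3a1, adjusted p = 0.375), 0.60 (Postn), 0.48 (Timp1), 0.47 (Tgfb2) and -0.76 (Spp1, -0.08 without vehicle apex replicate 2). Inflammatory genes had 0.67 ± 0.23 (Cxcl1, adjusted p = 0.466), 0.23 (Ccl2), 0.06 (Cxcl2), 0.25 (Cd68) and 0.18 (Hmox1). Vegfa had -0.13 and Pdk4 had -0.41.

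By camera, 10 of the 36 gene lists were called in the apex, 7 higher and 3 lower, and none of these calls held with an estimated correlation. As many lists were called in 13 of 100 splits of the same arrays, the real one included. Of the 53 measured members of the extracellular matrix list, 1 rose (Mfap4), 0 fell and 52 were not called, while 19 rose when adjusted over the list alone. The median log2 fold change was 0.37 (adjusted p = 9.25e-20 for the list, and adjusted p = 0.155 with an estimated correlation). Thbs4 (1.83 ± 0.31), Fbln2 (0.63 ± 0.12) and Col8a1 (1.33 ± 0.26) had the smallest p of its other members, at adjusted p = 0.0713, 0.0833 and 0.0918. The TGF-beta and Wnt signalling list had 0 of 29 members called and 7 risen when adjusted over the list alone, with a median of 0.35 (adjusted p = 1.76e-09, and adjusted p = 0.148 with an estimated correlation). Ccn5 (2.27), Ltbp2 (2.03), Fstl1 (0.88) and Ccn2 (1.17), which encodes connective tissue growth factor, led it. Fibroblast markers had 0 of 17 called and 8 risen when adjusted over the list alone, with a median of 0.39 (adjusted p = 1.06e-09, and adjusted p = 0.148 with an estimated correlation). Examples were Pi16 at 1.02 and Dpt at 0.52.

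Markers of monocytes and macrophages had 0 of 27 called in the apex and 2 risen when adjusted over the list alone (median 0.22, adjusted p = 0.000184, and adjusted p = 0.621 with an estimated correlation). The list included C1qa at 0.78 and Csf1r at 0.60. Nerve and Schwann cell markers had 0 of 18 called and 5 risen when adjusted over the list alone (median 0.21, adjusted p = 0.00437, and adjusted p = 0.23 with an estimated correlation). Members included S100b at 0.96 and Mbp at 0.62. The stretch and fetal gene programme had 1 of 16 members risen (Nppa), 15 not called and 3 risen when adjusted over the list alone (median 0.12, adjusted p = 0.00212, and adjusted p = 0.481 with an estimated correlation). The cell cycle list had 0 of 35 called on either scale (median 0.16, adjusted p = 0.028, and adjusted p = 0.4 with an estimated correlation). Examples were Ccnb2 at 0.53 and Top2a at 0.88. Of 18 settings, the cell cycle list lost its call in 4, nerve markers in 3 and the stretch programme in 2, the estimated correlation included. The nerve and cell cycle lists were mostly dim, with 1 of 18 and 5 of 35 members above a log2 signal of 8 in vehicle apex.

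Of the lower lists, fatty acid oxidation had 0 of 33 members called in the apex, also when adjusted over the list alone, with a median of -0.26 (adjusted p = 2.74e-06, and adjusted p = 0.481 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, had -0.32, and Angptl4 -1.02. Oxidative phosphorylation and the citric acid cycle had 0 of 45 called on either scale, with a median of -0.23 (adjusted p = 4.77e-09, and adjusted p = 0.545 with an estimated correlation). The list included Ndufa5 at -0.74 and Suclg1 at -0.27. This call ended under quantile normalization. Adult contractile and calcium handling genes had 0 of 18 called on either scale, with a median of -0.18 (adjusted p = 0.0154, and adjusted p = 0.699 with an estimated correlation). Members included Pln at -0.25 and Ryr2 at -0.29. The direction of this list turned under quantile normalization. The means of all 10 lists moved in the called direction on 5 of 5 PE apex arrays, except for the cell cycle list, with 4 of 5. The count of called probe sets in the apex ranged from 1 to 31 over the alternatives, and Sbsn and Mfap4 lost their calls in 10 and 12 of 21 settings each, Nppa in 1, the fit of only the apex arrays.

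The next comparison asked what PE changed in the outflow tract. Ccn5, a matrix-associated signalling protein, rose 30.7-fold (log2 4.94 ± 0.40, SE, n = 5 per group, limma adjusted p = 7.72e-08), from a mean signal of 192 ± 107 (SD) to 6859 ± 3555. Comp, a cartilage and tendon matrix protein, rose 27.5-fold (4.78 ± 0.39, adjusted p = 7.19e-08), from 35.8 ± 12.8 to 1649 ± 863. Nppa rose 23.9-fold (4.58 ± 0.48, adjusted p = 7.52e-07), from 699 ± 415 to 15610 ± 4326. The largest fall was that of Crybb1, a lens crystallin, 8.36-fold lower (-3.06 ± 0.38, adjusted p = 3.87e-06), and Fgf16, a growth factor of the heart, fell 6.40-fold (-2.68 ± 0.21, adjusted p = 7.19e-08).

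In all, 10720 of 31042 probe sets (34.5%) were called in the outflow tract, 6083 higher and 4637 lower, or 6296 of 14217 genes, 3741 higher and 2555 lower. With each array centred on its median, 4415 were higher and 5966 lower, and the median of all probe sets was -0.08 instead of 0.05. Other large rises were those of Car3 (29.4-fold, and 3.60 on the log2 scale on a dimmer probe set, a carbonic anhydrase abundant in fat and slow muscle), Rbp4 (23.4-fold, the retinol carrier), Ltbp2 (23.0-fold, a latent TGF-beta binding protein), Sfrp2 (22.2-fold, a secreted Wnt modulator), Col8a2 (18.8-fold), Cpxm2 (12.7-fold), Thbs4 (12.5-fold) and Grem1 (12.5-fold, a BMP antagonist). Col2a1, the collagen of cartilage, rose 14.0-fold (3.81 ± 0.73, adjusted p = 0.000359) on its brightest probe set, while 2 dimmer probe sets of the gene had 0.41 and 0.30 and were not called. Other large falls were those of Magix (7.54-fold), the adrenergic receptor gene Adra1d (6.21-fold), Cyp2e1 (6.18-fold), the glycerol channel gene Aqp7 (5.90-fold), Prkaa2 (5.58-fold, a catalytic subunit of AMP-activated kinase), Macrod1 (5.36-fold), Ky (5.19-fold), Lynx1 (5.08-fold), Phyhip (5.02-fold) and Akap6 (4.92-fold, an anchoring protein of muscle). The fall of Akap6 rests on 1 probe set, since another had -0.13 (adjusted p = 0.576). For each of these 24 genes, on the probe set given, all 5 PE arrays lay beyond all 5 vehicle arrays. The size of some changes depended on the value added before taking logs: with 64 and with 1 instead of 16, the log2 fold change was 3.55 and 5.26 for Rbp4, 2.83 and 4.64 for Col2a1, 2.49 and 4.75 for Grem1, and -2.25 and -3.77 for Crybb1. Adding 64 gave 3.87 for Comp, -2.10 for Magix, -1.89 for Adra1d and -1.66 for Phyhip. With PE outflow replicates 1 and 3 alone, Col2a1 had 6.01, Crybb1 -2.45, Aqp7 -1.86, Prkaa2 -1.76 and Akap6 -1.27. Col2a1 had 4.47 without PE outflow replicate 2 and 4.72 with array weights. These values all passed the test.

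Of the other index genes in the outflow tract, those that rose included Postn 7.01-fold (log2 2.81 ± 0.46), Timp1 5.21-fold (2.38 ± 0.26), Tgfb2 3.37-fold (1.75 ± 0.16), Col1a1 3.15-fold (1.66 ± 0.18) and Col3a1 1.91-fold (0.93 ± 0.12), at adjusted p from 1.83e-07 (Tgfb2) to 7.39e-05 (Postn). A dimmer probe set of Tgfb2 rose less, by 0.53 (adjusted p = 0.027). Spp1 (osteopontin) rose 4.28-fold (2.10 ± 0.80), with 4 of 5 PE arrays above all vehicle arrays and an adjusted p that rounds to 0.05, and lost this call in 15 of 20 settings, with 2.72 without PE outflow replicate 2. Nppb rose 1.99-fold (0.99 ± 0.26, adjusted p = 0.00517), with 3 of 5 PE arrays above all vehicle arrays. The chemokine genes Cxcl1 (2.29-fold, adjusted p = 0.000395) and Ccl2 (2.00-fold, adjusted p = 0.0226) and the macrophage gene Cd68 (2.44-fold, adjusted p = 8.74e-05) rose, and Ccl2 lost its call in 6 of 20 settings. Vegfa fell 2.59-fold (adjusted p = 0.000106), Pdk4, which restrains glucose oxidation, 2.89-fold (adjusted p = 0.000908), Atp2a2 1.67-fold (adjusted p = 0.00407) and Myh6 1.57-fold (adjusted p = 0.0135). Another probe set of Myh6 fell far more, with a log2 fold change of -3.44 (adjusted p = 3.8e-06). Pdk4 lost its call with PE outflow replicates 1 and 3 alone, Myh6 in the fit of only the outflow arrays, and Atp2a2 on 1 of its 4 other probe sets. Myh6 and Myh7 are near-identical in sequence, and their probe sets were not tested for shared signal. On their brightest probe sets Myh7 (-0.35) and Ankrd1 (-0.44) were not called, while their other probe sets fell (Myh7 -1.53, adjusted p = 0.00406, and Ankrd1 -0.82, adjusted p = 4.66e-05). The brightest were called in 3 settings for Myh7 and in 6 for Ankrd1. On the brightest probe sets of Myh6, Myh7, Ankrd1 and Atp2a2, 4 of 5 PE arrays lay below all vehicle arrays. PE outflow replicate 2, with a GAPDH ratio of 6.12, had the highest log2 signal of its group for Myh6 (15.91, others 14.36 to 14.8) and Ankrd1 (15.56, others 14.3 to 14.65). The highest signal of any probe set, controls included, was 112199 on replicate 2 and 41278 to 48010 on the other PE outflow arrays. On the vehicle outflow arrays it was 66788 to 77285. Whether an upper limit of the signal affected the brightest probe sets was not tested. Not called were Acta1 (-0.20, with the opposite sign under quantile normalization), Cxcl2 (0.34) and Hmox1 (0.50, called in 6 of 20 settings).

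By camera, 17 of 36 lists were called in the outflow tract, 12 higher and 5 lower. None held with an estimated correlation, and 5 of 100 splits of the same arrays, the real one included, called as many. The means of all 17 moved in the called direction on 5 of 5 PE arrays. Of 53 extracellular matrix genes, 50 rose, 0 fell and 3 were not called (52 risen when adjusted over the list alone), with a median log2 fold change of 1.66 (adjusted p = 2.69e-19, and adjusted p = 0.106 with an estimated correlation). Loxl1, an elastin crosslinking enzyme, rose by 2.74, Bgn (biglycan) by 2.47, Col18a1 by 2.16 and Col16a1 by 2.00. Of 32 matrix proteases and inhibitors, 20 rose, 2 fell and 10 were not called (24 and 2 when adjusted over the list alone, median 1.03, adjusted p = 8.62e-05, and adjusted p = 0.106 with an estimated correlation). Examples were Mmp23 at 2.04 and Serpinf1 at 2.05. Of 29 genes of TGF-beta and Wnt signalling, 22 rose, 0 fell and 7 were not called (22 when adjusted over the list alone, median 1.14, adjusted p = 1.5e-08, and adjusted p = 0.106 with an estimated correlation). Ccn2 rose by 3.17, Fst (follistatin) by 3.08 and Tgfb3 by 2.28. Fibroblast markers rose for 15 of 17 genes, with 0 fallen and 2 not called (15 when adjusted over the list alone, median 1.46, adjusted p = 4.09e-08, and adjusted p = 0.106 with an estimated correlation). The list included Pi16 at 2.20, S100a4 at 2.12 and Fap at 1.61.

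Of 33 genes of fatty acid oxidation, 30 fell, 0 rose and 3 were not called (31 fallen when adjusted over the list alone), with a median of -1.55 (adjusted p = 9.47e-19, and adjusted p = 0.106 with an estimated correlation). Hadh, an enzyme of beta-oxidation, fell by 1.97, Decr1 by 1.58, Cpt2 by 1.55 and Eci2 by 1.49. Of 45 genes of oxidative phosphorylation and the citric acid cycle, 44 fell, 0 rose and 1 was not called (44 when adjusted over the list alone), with a median of -1.18 (adjusted p = 7.5e-23, and adjusted p = 0.193 with an estimated correlation), among them the complex I subunit Ndufb8 (-1.78) and citrate synthase, Cs (-1.51). Of 24 glycolysis genes, 15 fell, 3 rose and 6 were not called (16 fallen and 4 risen when adjusted over the list alone, median -0.77, adjusted p = 5.05e-05, and adjusted p = 0.278 with an estimated correlation). Members included the muscle phosphofructokinase gene Pfkm at -2.00 and Ldha at -1.02. Of 18 adult contractile and calcium handling genes, 17 fell, 0 rose and 1 was not called (18 fallen when adjusted over the list alone, median -0.83, adjusted p = 1.55e-07, and adjusted p = 0.314 with an estimated correlation). Examples were the calcium release channel gene Ryr2 at -1.50, Cacna1c at -1.42 and Pln at -0.94. Of 22 channels and connexins, 14 fell, 1 rose and 7 were not called (17 fallen and 2 risen when adjusted over the list alone, median -1.17, adjusted p = 6.29e-06, and adjusted p = 0.193 with an estimated correlation). The list included Scn4b at -1.98, Kcnd3 at -1.42 and Cacnb2 at -1.45.

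Of 27 monocyte and macrophage markers, 23 rose, 0 fell and 4 were not called (24 when adjusted over the list alone, median 1.26, adjusted p = 2.29e-07, and adjusted p = 0.314 with an estimated correlation). Members included Adgre1 at 2.31 and the scavenger receptor gene Cd163 at 1.47. Mast cell markers rose for 8 of 14 genes, with 0 fallen and 6 not called (8 when adjusted over the list alone, median 0.96, adjusted p = 0.0098, and adjusted p = 0.314 with an estimated correlation). Examples were the protease genes Mcpt10 at 3.02, Cma1 at 2.27 and Cpa3 at 2.13. With PE outflow replicates 1 and 3 alone the mast cell list was not called (adjusted p = 0.058). Nerve and Schwann cell markers rose for 10 of 18 genes, with 0 fallen and 8 not called (10 risen and 1 fallen when adjusted over the list alone, median 1.15, adjusted p = 0.00554, and adjusted p = 0.193 with an estimated correlation). The list included Gap43, a protein of growing axons, at 3.45, and S100b at 3.06. Valve and cartilage matrix genes rose for 13 of 17, with 0 fallen and 4 not called (13 when adjusted over the list alone, median 1.71, adjusted p = 0.000244, and adjusted p = 0.193 with an estimated correlation). Members included Fmod at 3.17 and Col9a3 at 2.63. Of 35 cell cycle genes, 15 rose, 0 fell and 20 were not called (15 when adjusted over the list alone, median 0.46, adjusted p = 0.0116, and adjusted p = 0.193 with an estimated correlation). Examples were Foxm1 at 1.71 and Mki67, the proliferation marker, at 1.39.

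Of 18 complement genes, 11 rose, 2 fell and 5 were not called in the outflow tract (12 and 2 when adjusted over the list alone, median 0.93, adjusted p = 0.0116, and adjusted p = 0.314 with an estimated correlation). The list included C3 at 2.71 and Masp1 at -1.91. Of 38 chemokines and cytokines, 17 rose, 1 fell and 20 were not called (19 and 2 when adjusted over the list alone, median 0.54, adjusted p = 0.0402, and adjusted p = 0.314 with an estimated correlation). Members included Cxcl13 at 2.18, Ccl21 at 2.02 and Cxcl11 at -2.09. This call ended without vehicle outflow replicate 5 (adjusted p = 0.0744) or PE outflow replicate 1 (adjusted p = 0.0542). Of 28 interferon response genes, 10 rose, 0 fell and 18 were not called (10 when adjusted over the list alone, median 0.37, adjusted p = 0.0458, and adjusted p = 0.671 with an estimated correlation). Examples were Ifitm1 at 1.70 and Mx1 at 0.95. This list lost its call in 9 of 18 settings, among them the estimated correlation and leaving out PE outflow replicate 2. The 3' to 5' ratios were raised on PE outflow replicates 2, 4 and 5. Replicate 2, with the highest GAPDH ratio, had the lowest PE outflow mean of extracellular matrix (1.11 above vehicle, others 1.65 to 1.85) and of matrix proteases (0.60, others 1.04 to 1.16). With replicates 1 and 3 alone, 7307 probe sets were called, 6875 of them among the 10720, and 15 lists. With the GAPDH ratio as a covariate, 10015 probe sets were called, 8308 of them among the 10720, and 16 lists. In simulated data with 200 changed probe sets and each group's own spread, 31.8% of the outflow calls were of unchanged probe sets, against 9.71% with only the compared groups in the fit, which called 8871 probe sets here. Such a share depends on how many probe sets truly change. It cannot be carried over to the 10720 calls of the outflow tract.

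**Figure D2:**
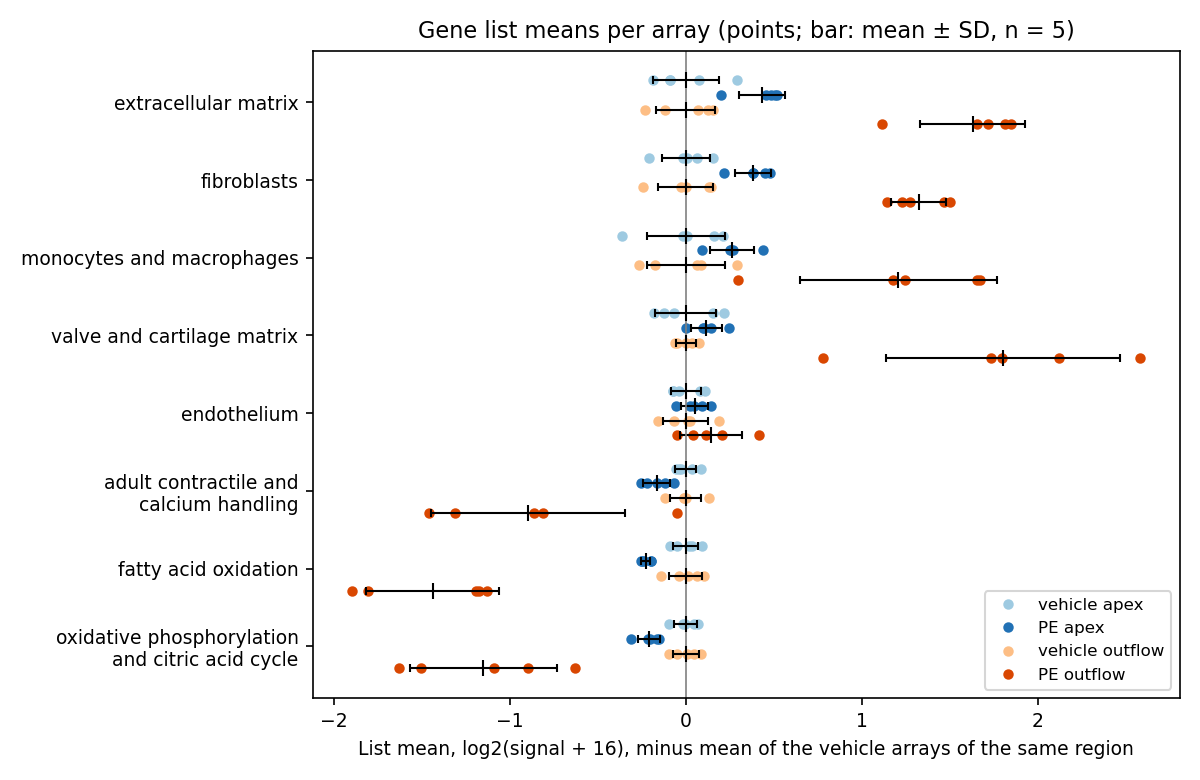
Mean log2 signal of 8 gene lists on each array, as the difference from the mean of the vehicle arrays of the same region, with 1 point per array and bars for mean ± SD (n = 5). In PE outflow the extracellular matrix list had a mean of 1.63 ± 0.30 and fatty acid oxidation -1.44 ± 0.38, against 0.43 ± 0.13 and -0.23 ± 0.03 in PE apex, while endothelial markers had 0.14 ± 0.18 in PE outflow.

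Whether the effect of PE differed between the regions was tested directly. It was higher in the outflow tract for the following genes. For Comp the difference was 5.22 ± 0.55 on the log2 scale (limma adjusted p = 7.08e-05, n = 5 per group), for the BMP antagonist Grem1 3.90 ± 0.68, for the collagenase gene Mmp13 3.84 ± 0.76, for Col2a1 3.80 ± 1.03, for the fatty acid desaturase gene Scd 3.59 ± 0.43 and for Cpxm2 3.47 ± 0.44. It was more negative in the outflow tract for Ppara, a regulator of fatty acid oxidation (-2.62 ± 0.45, adjusted p = 0.000947), Prkaa2 (-2.53 ± 0.48), Crybb1 (-2.52 ± 0.53), Akap6 (-2.47 ± 0.45), Magix (-2.39 ± 0.44) and the phosphodiesterase gene Pde3a (-2.37 ± 0.57). The calls of Col2a1 and Akap6 rest on 1 probe set each, since others had 0.76 and 0.34 (Col2a1) and -0.34 (Akap6) and were not called. Several of these genes had signals near the added 16 in 1 or more groups, such as Scd with 5.88 in PE apex and Ppara with 16.03 in PE outflow. With 64 and with 1 added instead, the difference was 4.12 and 5.86 for Comp, 2.59 and 5.25 for Grem1, 2.24 and 6.51 for Mmp13, 2.82 and 4.71 for Col2a1, and 2.24 and 5.08 for Scd. It was -1.46 and -3.98 for Ppara, -1.79 and -3.19 for Crybb1, -1.18 and -3.99 for Pde3a, and -1.66 for Magix with 64. With PE outflow replicates 1 and 3 alone, Mmp13 had 4.46, Col2a1 6.00, Ppara -2.01, Prkaa2 -1.81, Crybb1 -1.91 and Akap6 -1.44. Col2a1 had 4.46 without PE outflow replicate 2 and 4.66 with array weights. All of these values passed the test. In all, 5567 probe sets differed in PE effect, 3056 with a higher and 2511 with a lower value in the outflow tract, or 3451 genes. With each array centred on its median, 2046 were higher and 3241 lower.

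Among the index genes, the PE effect was larger in the outflow tract for Postn (difference 2.21 ± 0.65), Timp1 (1.90 ± 0.36), Tgfb2 (1.28 ± 0.22), Cd68 (1.04 ± 0.30), Col1a1 (1.03 ± 0.25) and Col3a1 (0.54 ± 0.17), and more negative for Vegfa (-1.24 ± 0.33), at adjusted p from 0.00102 (Tgfb2) to 0.0296 (Col3a1). Another probe set of Tgfb2 had 0.16 (adjusted p = 0.73), so its call rests on 1 probe set, while another of Col1a1 had 1.90 (adjusted p = 0.00238). Col3a1 lost its call in 9 of 28 settings, Cd68 in 3 and Postn in 1. Mfap4 also differed (0.87, adjusted p = 0.014). For Nppa the difference was 0.80 ± 0.67 (adjusted p = 0.48) and for Sbsn 0.18 (adjusted p = 0.825), so no difference between regions was detected for these. For 5 genes the difference was not called on the brightest probe set but was on another: Myh6 (-0.45, other -3.18, adjusted p = 0.00148), Myh7 (-0.38, other -2.21, adjusted p = 0.00899), Ankrd1 (-0.36, other -0.83, adjusted p = 0.00398), Pdk4 (-1.12, other -1.49, adjusted p = 0.0308) and Atp2a2 (-0.57), with 2 of 4 others called (-0.71, adjusted p = 0.00245, and -1.0, adjusted p = 0.0494). The differences of the remaining index genes were not called: Spp1 (2.86 ± 1.14, adjusted p = 0.0905, called in 3 of 28 settings, with 2.18 without vehicle apex replicate 2 and a call at 3.48 without PE outflow replicate 2), Ccl2 (0.78), Cxcl1 (0.53), Acta1 (-0.42), Hmox1 (0.32), Cxcl2 (0.28) and Nppb (-0.19).

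Of the 36 lists, 14 (17 with a block for the rat) were called for the difference between regions. Of the 14, 9 were more positive and 5 more negative in the outflow tract. None held with an estimated correlation, and 11 of 100 splits, with the real one, called as many. Extracellular matrix differed for 38 of 53 genes, all higher (43 when adjusted over the list alone, median 1.18, adjusted p = 1.49e-15, and adjusted p = 0.191 with an estimated correlation). The list included Loxl1 at 2.03 and Col16a1 at 1.78. TGF-beta and Wnt signalling had 18 of 29 higher, 0 lower and 11 not called (19 when adjusted over the list alone, adjusted p = 9.59e-07). Members included Fst at 2.67 and the activin gene Inhba at 2.21. Matrix proteases had 17 of 32 higher, 0 lower (18 when adjusted over the list alone, adjusted p = 7.59e-05) and fibroblast markers 12 of 17 higher, 0 lower (13 when adjusted over the list alone, adjusted p = 9.59e-07). For these 3 lists, too, adjusted p = 0.191 with an estimated correlation. Fatty acid oxidation had 27 of 33 lower, 0 higher (29 lower and 1 higher when adjusted over the list alone, median -1.30, adjusted p = 2.5e-18, and adjusted p = 0.191 with an estimated correlation). Examples were Acot2 at -1.82 and Cpt2 at -1.31. Oxidative phosphorylation and the citric acid cycle had 31 of 45 lower, 0 higher (42 when adjusted over the list alone, median -0.94, adjusted p = 3.65e-21, and adjusted p = 0.204 with an estimated correlation).

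Glycolysis had 12 of 24 genes lower and 3 higher in the difference (14 and 3 when adjusted over the list alone, adjusted p = 1.68e-05, and adjusted p = 0.255 with an estimated correlation). Contractile and calcium handling genes had 6 of 18 lower, 0 higher (10 when adjusted over the list alone, adjusted p = 2.69e-06, and adjusted p = 0.408 with an estimated correlation), and channels and connexins 10 of 22 lower, 0 higher (13 lower and 1 higher when adjusted over the list alone, adjusted p = 6.6e-06, and adjusted p = 0.204 with an estimated correlation). Higher were 14 of 27 monocyte and macrophage markers (19 when adjusted over the list alone, adjusted p = 9.04e-06, and adjusted p = 0.411 with an estimated correlation), 10 of 18 nerve and Schwann cell markers (10 when adjusted over the list alone, adjusted p = 0.00663, and adjusted p = 0.204 with an estimated correlation) and 8 of 17 valve and cartilage matrix genes (8 when adjusted over the list alone, adjusted p = 0.000163, and adjusted p = 0.204 with an estimated correlation), with 0 lower in each. Mast cell markers had 5 of 14 higher, 0 lower (7 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0099, and adjusted p = 0.352 with an estimated correlation), and complement 8 of 18 higher and 2 lower (8 and 2 when adjusted over the list alone, adjusted p = 0.0343, and adjusted p = 0.408 with an estimated correlation). The mast cell list lost its call in 2 of 27 settings and complement in 4, the estimated correlation included. With PE outflow replicates 1 and 3 alone, whose GAPDH and beta-actin ratios lay within the range of the vehicle arrays, 3646 probe sets differed in PE effect, and 13 lists.

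**Figure D3:**
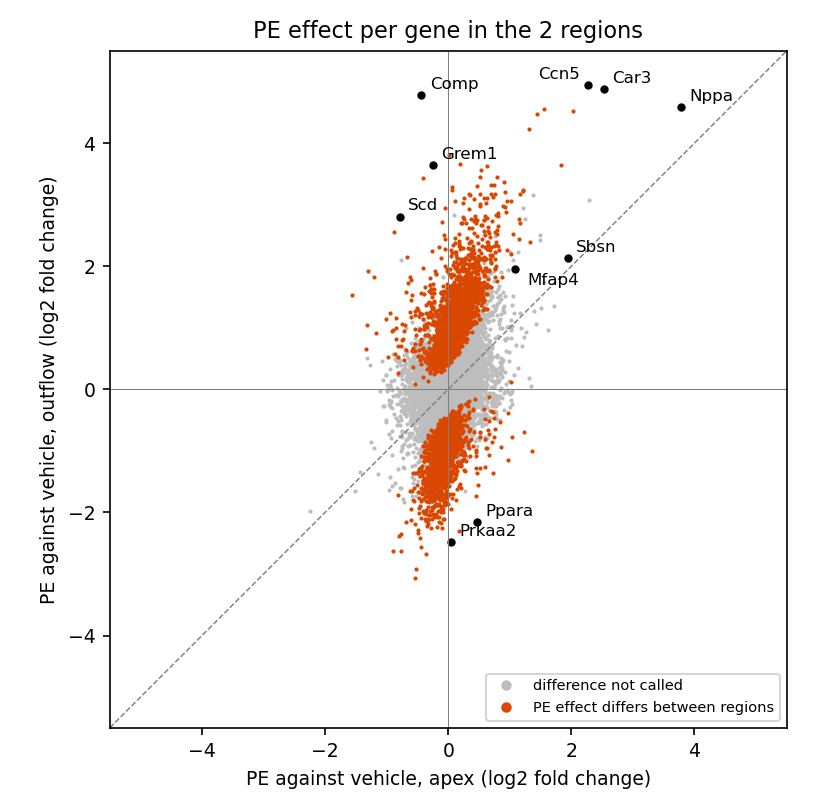
Log2 fold change of PE against vehicle for each of 14217 genes, in the apex (horizontal) and in the outflow tract (vertical), with orange points for genes whose PE effect differed between regions at an adjusted p under 0.05. Nppa lies at 3.78 and 4.58, and Comp at 4.78 in the outflow tract.

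Across 14217 genes, the PE effects in the apex and in the outflow tract had a Pearson r of 0.411 and a Spearman rho of 0.393, and 63.5% had the same sign. Genes are not independent replicates, and the same rats gave both regions, which adds a correlation of its own. When the rats were split in other ways that mixed the treatments, the median r was 0.122 and the highest 0.381.

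Outflow and apex were also compared within each treatment, which asked how the regions of the right ventricle differ without and with PE. In vehicle rats no gene and no list passed the test: 0 of 31042 probe sets were called by limma, the smallest adjusted p was 0.393, and 1152 (3.71%) had an unadjusted p under 0.05. A block for the rat also gave 0, and of the lists camera called 0, camera with an estimated correlation 0 and fry 0. Adipocyte markers had the smallest list p, with 0 of 17 members called on either scale, a median of 0.19 and an adjusted p of 0.153. Camera called 3 lists without vehicle apex replicate 2, and 3 without vehicle outflow replicate 5. In a fit of the vehicle arrays alone, 1 dim probe set passed, for the transcription factor gene Sox4 (log2 -1.55 ± 0.15, adjusted p = 0.031, signal 8.24 ± 2.35 in outflow and 56.0 ± 14.3 in apex, n = 5 each), which is named after its value was seen.

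In PE rats, 8924 probe sets differed between the regions, 4971 higher and 3953 lower in the outflow tract, or 5371 genes, 3164 higher and 2207 lower. Comp was 27.8-fold higher in the outflow tract (log2 4.80 ± 0.39, limma adjusted p = 3.81e-07, n = 5 per group), with a mean signal of 1649 ± 863 (SD) against 34.3 ± 6.93 in the apex. Rbp4 was higher by 3.93 on the log2 scale, Scd by 3.76, Grem1 by 3.75, Car3 by 3.62, Cpxm2 by 3.46, Col2a1 by 3.38, the cochlear matrix gene Coch by 3.37, the smooth muscle gene Cnn1 by 3.26, the bone matrix gene Ibsp by 3.26, Ccn3 by 3.25 and the smooth muscle actin gene Actg2 by 3.19. For Ibsp 4 of 5 outflow arrays lay above all apex arrays, and the dimmer probe sets of Col2a1 had 0.54 and -0.15 and were not called, while that of Car3 was higher by 2.89. Prkaa2 was lower in the outflow tract (-2.29), as were Akap6 (-2.25), Crybb1 (-2.23), the potassium channel gene Kcnh2 (-2.11), Klhl38 (-2.09), Phlda1 (-2.08), Aqp7 (-2.08), Fgf16 (-2.04), Txlnb (-2.01), LOC100909396 (-1.99), Ppara (-1.97) and Slc4a1 (-1.97). Another probe set of Slc4a1 had -0.42 (adjusted p = 0.417), and its call also ended with PE outflow replicates 1 and 3 alone (-0.99). Other probe sets of Akap6 and Txlnb were lower by less, at -0.57 and -1.27. With 64 and with 1 added before taking logs, the difference between regions was 2.32 and 5.41 for Scd, 2.53 and 4.91 for Grem1, 2.61 and 3.98 for Col2a1, 2.09 and 5.17 for Coch, 2.23 and 4.23 for Ibsp, -1.52 and -2.89 for Crybb1, and -1.04 and -3.20 for Ppara. Adding 64 gave 3.89 for Comp, 3.21 for Rbp4, -1.41 for Kcnh2 and -1.34 for Slc4a1. With PE outflow replicates 1 and 3 alone, Col2a1 had 5.58, Ibsp 4.38, Coch 4.14, Prkaa2 -1.56, Akap6 -1.22, Crybb1 -1.61, Kcnh2 -1.03, Klhl38 -1.41, Phlda1 -1.21, Aqp7 -1.37, Txlnb -1.33 and Ppara -1.36. Without PE outflow replicate 2, Col2a1 had 4.045 and Ibsp 4.15, and Coch had 4.04 without replicate 5. Array weights gave 4.21 for Col2a1 and 3.85 for Ibsp. These values, too, passed the test. With each array centred on its median, 3707 probe sets were higher and 4875 lower.

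Of the 36 lists, 15 (16 with a block for the rat) were called between the regions of PE rats. Of the 15, 10 were higher and 5 lower in the outflow tract. None held with an estimated correlation, and 27 of 100 splits that ignored the pairs of arrays, with the real one, called as many. Extracellular matrix had 46 of 53 genes higher, 0 lower (49 when adjusted over the list alone, median 1.32, adjusted p = 2.91e-17), TGF-beta and Wnt signalling 21 of 29 higher, 0 lower (21 when adjusted over the list alone, adjusted p = 1.23e-07), matrix proteases 18 of 32 higher and 2 lower (22 and 3 when adjusted over the list alone, adjusted p = 6.39e-05) and fibroblast markers 13 of 17 higher, 0 lower (14 when adjusted over the list alone, adjusted p = 2.91e-07). Nerve and Schwann cell markers had 10 of 18 higher, 0 lower (10 when adjusted over the list alone, adjusted p = 0.00109). The list included Gap43 at 3.17 and Gfap at 2.67. Fatty acid oxidation had 29 of 33 lower and 1 higher (29 and 1 when adjusted over the list alone, median -1.29, adjusted p = 3.64e-17). Members included Hadh at -1.69 and Acadm at -1.36. For each of these 6 lists adjusted p = 0.118 with an estimated correlation. Oxidative phosphorylation and the citric acid cycle had 43 of 45 lower, 0 higher (44 when adjusted over the list alone, median -0.95, adjusted p = 8.23e-22), and channels and connexins 13 of 22 lower and 2 higher (18 and 2 when adjusted over the list alone, adjusted p = 4.34e-06), for which adjusted p = 0.194 with an estimated correlation.

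Valve and cartilage matrix had 13 of 17 genes higher in the outflow tract of PE rats, 0 lower (14 when adjusted over the list alone, adjusted p = 3.23e-05, and adjusted p = 0.153 with an estimated correlation). Examples were Fmod at 2.95 and Chad at 2.45. Mast cell markers had 8 of 14 higher, 0 lower (9 when adjusted over the list alone, adjusted p = 0.00278, and adjusted p = 0.259 with an estimated correlation), and monocyte and macrophage markers 21 of 27 higher, 0 lower (23 when adjusted over the list alone, adjusted p = 2.13e-06, and adjusted p = 0.363 with an estimated correlation). Complement had 10 of 18 higher and 2 lower (11 and 2 when adjusted over the list alone, adjusted p = 0.0385, and adjusted p = 0.363 with an estimated correlation), and chemokines and cytokines 15 of 38 higher and 2 lower (19 and 2 when adjusted over the list alone, adjusted p = 0.0385, and adjusted p = 0.353 with an estimated correlation). Of 17 settings, complement lost its call in 5 and chemokines and cytokines in 4, the estimated correlation included. The others left out PE outflow replicates 1, 3, 4 or 5 for complement (adjusted p up to 0.0595), and PE outflow replicates 1 or 4 or PE apex replicate 5 for chemokines (adjusted p up to 0.0642). Glycolysis had 13 of 24 lower and 3 higher (14 and 3 when adjusted over the list alone, adjusted p = 3.94e-05, and adjusted p = 0.271 with an estimated correlation), and contractile and calcium handling genes 13 of 18 lower, 0 higher (14 when adjusted over the list alone, adjusted p = 1.17e-06, and adjusted p = 0.363 with an estimated correlation). With PE outflow replicates 1 and 3 alone, 5320 probe sets differed between the regions of PE rats, and 15 lists. The regional differences of PE rats as such were set against those of vehicle rats by the test of the difference in PE effect, which is the same contrast.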

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

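The tests of degraded RNA on 1 array, of RNA quality, of a lower share of muscle cells, of attached tissue and of the same RNA on paired arrays were chosen only after the result was seen, as was the alternative with only PE outflow replicates 1 and 3. Samples far from the others were sought in 280 groups of 5 arrays (gap to the nearest array above 0.71 of the range). Chance gives about 1 such group in 20, and 27 of the 280 (9.64%) had one, 9 of them PE outflow replicate 2.

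PE outflow replicate 2 had a GAPDH 3' to 5' ratio of 6.12 (others 1.70 to 2.34), a beta-actin ratio of 11.5 (others 2.92 to 4.54), a mean log2 signal of the hybridization controls of 13.45 (others 11.66 to 12.07) and a mean r of 0.929 with its group (others 0.959 to 0.963). Its list means were 11.20 for extracellular matrix (others 11.74 to 11.94) and 9.02 for matrix proteases (others 9.46 to 9.58), and its log2 signals 15.91 for Myh6, 15.56 for Ankrd1 and 10.50 for Sfrp2 (others 12.84 to 13.69). Among the ratios of the control probe sets, which the main comparisons did not use, PE outflow replicates 4 and 5 also exceeded the highest vehicle array. Their GAPDH ratios were 2.20 and 2.34 against 1.83, and their beta-actin ratios 4.0 and 4.54 against 3.14.

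In other PE outflow arrays, Tgfb2 had a log2 signal of 8.97 on replicate 1, Pdk4 11.85 and Scd 9.59 on replicate 3. In PE apex, replicate 5 had a hexokinase control ratio of 10.2 (others 4.07 to 5.59), Hmox1 at 7.94 and Pde3a at 5.32, replicate 2 an extracellular matrix mean of 10.23 and replicate 1 a channel and connexin mean of 8.75. In vehicle outflow, replicate 5 had means of 6.82 for cell cycle and 11.81 for glycolysis, Cxcl2 at 4.16, Fgf16 at 10.66 and Mmp13 at 5.42. Replicate 4 of that group had a stretch programme mean of 10.54, replicate 2 Ccl2 at 10.49 and replicate 1 Pde3a at 5.11. In vehicle apex, Mfap4 was 11.96 on replicate 2 and Cd68 8.04 on replicate 4.

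A test of the difference itself (limma, adjusted p under 0.05) separated the PE effect in the outflow tract from that in the apex at 5567 probe sets. Among named genes, the outflow effect was higher on the log2 scale for Comp (5.22), Grem1 (3.90), Mmp13 (3.84), Col2a1 (3.80), Scd (3.59), Cpxm2 (3.47), Sfrp2 (3.04), Rbp4 (3.0), Col8a2 (2.92), Ccn5 (2.67), Ltbp2 (2.50), Postn (2.21), Timp1 (1.90), Thbs4 (1.82), Tgfb2 (1.28), Cd68 (1.04), Col1a1 (1.03), Mfap4 (0.87) and Col3a1 (0.54). It was lower for Ppara (-2.62), Prkaa2 (-2.53), Crybb1 (-2.52), Akap6 (-2.47), Magix (-2.39), Pde3a (-2.37), Fgf16 (-2.31), Aqp7 (-2.11), Macrod1 (-1.97), Adra1d (-1.87), Phyhip (-1.84), Cyp2e1 (-1.74), Lynx1 (-1.58), Ky (-1.57) and Vegfa (-1.24). Other probe sets of Col2a1 (0.76 and 0.34), Tgfb2 (0.16) and Akap6 (-0.34) were not called. Among lists, the median difference was 1.34 for valve and cartilage matrix, 1.18 for extracellular matrix, 1.04 for mast cells, 1.03 for fibroblasts, 0.98 for nerve and Schwann cells, 0.96 for TGF-beta and Wnt signalling, 0.95 for monocytes and macrophages, 0.74 for matrix proteases, 0.64 for complement, -0.66 for glycolysis, -0.68 for contractile genes, -0.94 for channels and connexins, -0.94 for oxidative phosphorylation and -1.30 for fatty acid oxidation. No list was called for the difference with an estimated correlation.

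The array of PE outflow replicate 2 stood apart from its group. A wrong group label is argued against: on an axis from vehicle outflow (0) to the other PE outflow arrays (1) it lay at 0.629, above every array of the other groups (up to 0.216), and below the other PE outflow arrays (0.698 to 1.27). Degraded RNA or short labelled copies may account for it, since its GAPDH ratio was 2.62 times and its beta-actin ratio 2.54 times that of the next highest array. The third control does not single it out, with a hexokinase ratio of 10.2 against 12.01 on replicate 5. This control says little, since its 5' signals of 15.7 and 16.1 on these arrays lay near the added 16. A biological difference of this rat was not tested and stays open. Its apex array had a GAPDH ratio of 1.57, yet the lowest PE apex position on the same axis (0.117, others 0.169 to 0.216). The extracellular matrix mean of that apex array was also the lowest of its group (10.23, others 10.48 to 10.54).

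PE outflow differed from vehicle outflow at 10720 probe sets, and RNA quality as the whole cause is argued against, since replicates 1 and 3, with GAPDH and beta-actin ratios in the vehicle range, still gave 7307 calls, 6875 of them shared. The hexokinase ratio of replicate 3 (6.42, from a dim 5' signal of 55.4) was slightly above every vehicle array (up to 6.16). A part of RNA quality in these effects stays open. A lower share of muscle cells that raises all other cell types alike, the endothelium included, is argued against by the mean of the endothelial list. A lower share that does not raise the endothelium was not tested and stays open. Fibroblast markers rose more than endothelial markers on 5 of 5 arrays, by 1.18 ± 0.32 (SD) on the log2 scale. Of their members, 5 of 17 and 1 of 19 are in another list. Endothelial markers had a PE outflow mean of 0.14 above vehicle, lymphocytes 0.39, neutrophils 0.07 and red blood cells 0.05. In vehicle outflow, 18 of 19 endothelial members were above a log2 signal of 8. Only 4 of 21 lymphocyte, 2 of 11 neutrophil and 2 of 6 red blood cell members were. The means of these dim lists cannot show the absence of a rise. Several other cell types rose nearly alike: fibroblasts 1.32, adipocytes 1.22, macrophages 1.21, mast cells 1.09, nerve 1.06, smooth muscle 1.0 and mesothelium 0.84. Of these, mast cells (1 of 14), nerve (1 of 18) and mesothelium (3 of 13) also had few members above a log2 signal of 8 in vehicle outflow. Contractile genes had -0.90 and channels -0.97, a pattern that a lower share would also give. The members most abundant in PE outflow, a choice that favours risen genes, ran against the fibroblast and endothelial means. Endothelial Vwf, Lyve1 and Eng had 7720, 4280 and 4001 in PE against 2145, 1948 and 1863 in vehicle outflow. Fibroblast Col3a1, Gsn and Vim had 36060, 29380 and 27350 against 18940, 29170 and 15140. A lower share as a part of the change stays open. Valve, vessel or cartilage tissue taken with the piece cannot be told apart from a change in the muscle wall. All 5 PE arrays had a valve and cartilage mean above every vehicle outflow array, while no list was called between the vehicle regions with all arrays. The dissection has no sort that would remove such tissue. Of the 17 members, 2 were above a log2 signal of 8 in vehicle outflow, and 1 is in another list. The members most abundant in PE outflow, Omd, Prelp and Fmod, had 3798 ± 1819, 2940 ± 941 and 2247 ± 1258 there, against 651 ± 164, 993 ± 134 and 203 ± 77.2. An effect of PE on this region, which the design names, is a hypothesis beside it.

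Vehicle regions differed at 0 probe sets by limma (1152 at an unadjusted p under 0.05) and PE regions at 8924. For the same RNA on both arrays of a vehicle rat, deviations of paired vehicle arrays correlated at a mean of 0.224. Paired PE arrays, whose regions differed, had a similar mean of 0.210. No sample was measured on 2 arrays, so the correlation that copies would give is not known. This explanation is therefore not excluded. A test too weak to call regional differences is argued against only for 2-fold changes of brighter probe sets that occur beside many other changes. In simulated data 71.3% of these were called, among 200 changed probe sets outside the 40% dimmest, 4-fold ones included. Smaller changes, those of dim probe sets and a few isolated 2-fold changes stay open. Still open are the same RNA on paired vehicle arrays, a difference in how PE acts on the regions and tissue taken with the outflow piece. As parts, RNA quality of the PE outflow arrays (5320 calls with replicates 1 and 3 alone) and a lower share of muscle cells stay open too. The test of the difference in PE effect was chosen before the data were examined, but it cannot tell these apart.

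Other splits of the same arrays into groups of 5 were drawn 100 times per comparison, the real one included. For counts of probe sets, chance is excluded in the outflow tract (1 split as large, 10720 called, highest other 5102). In the apex 1 split was as large (4 called, highest other 2), but several alternatives called 1 probe set there. Splits were drawn only for the main setting, so chance is not excluded for the apex across settings. For the difference 1 split was as large (5567, highest other 1). Its other splits mix PE with vehicle rats, so a PE effect common to both regions widens their spread and lowers their counts. They cannot decide about chance for the difference. Between PE regions, where the arrays are paired by rat, the splits that part each pair number 16, too few for a share under 0.05 (8924, highest other 1995). Splits that ignore the pairs mostly part fewer of them, and 1 of 100 was as large (highest other 3725). For counts of lists, chance is not excluded in the apex, the outflow tract or the difference: 13 splits were as large in the apex (10 called, highest other 14), 5 in the outflow tract (17, 19) and 11 for the difference (14, 18). Between PE regions 27 of the splits that ignore the pairs had as many lists (15, 21). Between vehicle regions the counts of probe sets and of lists were 0 (highest other 2 and 7), so that all 100 splits are as large whatever the data, and nothing is said about chance. For the correlation of PE effects between regions, 1 split of the rats was as large (0.411, highest other 0.381).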

How the results depend on the processing

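The alternatives with only PE outflow replicates 1 and 3, with the GAPDH ratio, and without PE outflow replicate 2 in the apex, between vehicle regions and for the correlation were chosen after seeing the data, the others before. The count of called probe sets in the outflow tract stayed within 1.5 times of 10720 in every alternative run, with 9446 to 11525 when single arrays were left out, and those between PE regions had 7420 to 9783. The count in the apex (4) was 1 with quantile normalization, at an adjusted p under 0.01 (a stricter threshold) and with a block by replicate number, which pairs vehicle with PE rats that the data did not pair, while the rat as a random effect gave 4. It was 7 with the GAPDH ratio. It was 15 without dim probe sets (fewer were tested), 17 after adding 64, 22 with only PE outflow replicates 1 and 3, 23 with an intensity trend and 31 with array weights. Leaving out single arrays gave 1 to 30 in the apex: 30 without PE outflow replicate 2, 23 without PE apex replicate 2, 2 without vehicle apex replicates 3 or 5, and 1 without PE apex replicates 1, 4 or 5 or vehicle apex replicate 4. For the difference in PE effect (5567), an adjusted p under 0.01 gave 2689, PE outflow replicates 1 and 3 alone 3646 and single arrays left out 4511 to 7127. Between PE regions (8924), replicates 1 and 3 alone gave 5320. Between vehicle regions (0), the fit of these groups alone gave 1. The PE outflow arrays enter the apex comparison only through the shared estimate of the spread. Its counts of 30 and 22 without some of them reflect that estimate, while the fold changes are the same. The other fits with replicates 1 and 3 alone or without an array hold fewer arrays, and beyond this the cause was not tested. A fit of only the compared groups is the same fit for the difference, so it has no value there.

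With an estimated correlation between genes, the count of called lists was 0 in the apex, the outflow tract, the difference and between PE regions, where most lists have an estimate above the preset 0.01. Leaving out single arrays gave 9 to 14 lists in the apex, 15 to 17 in the outflow tract, 13 to 16 for the difference, 13 to 17 between PE regions and 0 to 3 between vehicle regions, with 3 without vehicle apex replicate 2 and 3 without vehicle outflow replicate 5. The correlation of PE effects between regions (0.411) was 0.560 over genes above the dim limit and 0.600 over genes called in either region, and 0.370 to 0.424 without single rats. The cause was not tested.

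Of the values of named genes under alternatives, 2597 kept their direction and side of the threshold, 70 lost a call, 38 gained one and 21 turned direction. For called lists these were 1032, 86, 0 and 1. Lists not called had 55 calls in 2373 values. The list of contractile genes in the apex turned to an adjusted p of 0.954 with quantile normalization (0.000161 to 0.954 over its alternatives). None of the genes that turned was called there except Col2a1 between PE regions. With quantile normalization the log2 values were 0.0913 for Ankrd1 and 0.0339 for Atp2a2 in the apex and 0.187 for Acta1 in the outflow tract. Cxcl2 in the apex was -0.00746 after adding 64, -0.0784 with array weights and -0.18 to 0.42 without single arrays, under 0 without vehicle apex replicates 3 (-0.141) and 4 and PE apex replicates 2 (-0.0546) and 3 (-0.141). Without single arrays it was -0.0213 (vehicle outflow replicate 5) to 0.48 in the outflow tract and -0.0811 (the same array) to 0.51 for the difference, with -0.0809 without vehicle apex replicate 2. Myh7 in the apex was -0.0124 (PE apex replicate 4) to 0.0728 without single arrays, with -0.0119 without vehicle apex replicate 2. The difference for Nppb was -0.37 to 0.0416 without single arrays, above 0 without vehicle outflow replicate 2, and 0.103 with PE outflow replicates 1 and 3 alone. Other probe sets gave 0.00734 for Ankrd1 and 0.0345, 0.0527 and 0.0975 for Atp2a2 in the apex, and -0.15 for Col2a1 between PE regions. The cause was not tested. Signal over background limits the dim probe sets: signals under the added 16 carry little of a fold change, and 3842 to 5246 probe sets per PE outflow array lay there. Every alternative chosen before the data were examined was run.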

Other observations

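Lists that were not called in the outflow tract by camera still held genes that PE changed there. Of all 14217 genes, 44.3% were called in that region, 3741 higher and 2555 lower, so such counts alone do not mark a list. Smooth muscle and pericyte markers rose for 10 of 17 genes and fell for 4, with 3 not called (10 and 4 when adjusted over the list alone, median log2 fold change 1.66, adjusted p = 0.128). Examples were the smooth muscle actin gene Acta2 at 2.34, Mylk at 1.93 and Des, the desmin gene that heart muscle also expresses, at -1.30. Adipocyte markers rose for 9 of 17 and fell for 5 (10 and 5 when adjusted over the list alone, median 1.60, adjusted p = 0.264). The list included Scd at 2.81, Fasn at 1.60 and Cidea at -1.70. Mesothelial markers rose for 6 of 13 and fell for 1 (7 and 1 when adjusted over the list alone, median 0.62, adjusted p = 0.0899). Members included Krt19 at 2.77. Endothelial markers rose for 5 of 19 and fell for 2 (5 and 2 when adjusted over the list alone, median 0.01, adjusted p = 0.898). Examples were Vwf at 1.84 and Eng at 1.11. Receptors of the renin-angiotensin, endothelin, adrenergic and natriuretic systems rose for 10 of 22 and fell for 3 (10 and 3 when adjusted over the list alone, adjusted p = 0.33). The list included the angiotensin receptor gene Agtr1a at 2.45 and Adra1b at -1.73. Antigen presentation rose for 11 of 24 and fell for 1 (11 and 1 when adjusted over the list alone, adjusted p = 0.22). Members included RT1-Db1 at 1.20 and Psme1 at -0.94. Outflow tract regulators rose for 4 of 34 and fell for 8 (4 and 8 when adjusted over the list alone, adjusted p = 0.194). Examples were Bmp4 at 1.66, Bmp2 at 1.20 and the cardiac transcription factor genes Nkx2-5 at -1.86 and Gata5 at -1.50. Each of these values comes from arrays of which replicates 2, 4 and 5 had raised 3' to 5' control ratios.

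For the other lists not called in the outflow tract, the members risen and fallen are given, with the counts when adjusted over the list alone in brackets. They, too, stand beside 44.3% of all genes called. The stretch and fetal programme had 4 and 3 of 16 (4 and 4, adjusted p = 0.893), with Xirp1 at -1.24 and Uchl1 at 1.60. The hypoxia response had 8 and 6 of 22 (8 and 6, adjusted p = 0.814), with Ndrg1 at 1.24 and Egln1 at -1.08. Oxidative stress and arginine metabolism had 8 and 9 of 31 (10 and 10, adjusted p = 0.471), with the catalase gene Cat at -1.15 and Cybb at 1.57. Immediate early genes had 8 and 1 of 23 (8 and 1, adjusted p = 0.152), with Egr2 at 1.65 and Myc at 1.06. Heat shock and unfolded protein response had 8 and 6 of 25 (8 and 7, adjusted p = 0.898), with Creld2 at 1.55 and Hspd1 at -0.84. The circadian clock had 1 and 1 of 17 (0 and 0, adjusted p = 0.893), lymphocytes 5 and 1 of 21 (5 and 1, adjusted p = 0.33), neutrophils 2 and 1 of 11 (2 and 1, adjusted p = 0.924) and red blood cells 1 and 1 of 6 (1 and 1, adjusted p = 0.898). Atrial muscle had 4 and 2 of 13 (4 and 4, adjusted p = 0.981), with Nr2f2 at 1.64 and Tbx5 at -1.09. The conduction system had 5 and 2 of 18 (5 and 3, adjusted p = 0.898), with Smoc2 at 1.54 and Irx3 at -1.46. Skeletal muscle had 5 and 2 of 20 (5 and 2, adjusted p = 0.786), with Myl1 at 2.88 and Casq1 at -1.37. Median, mean and test differed in sign for hypoxia (0.20, -0.0071, lower), the stretch programme (-0.00055, 0.27, lower) and atrial muscle (-0.05, 0.40, lower). For oxidative stress, the clock, neutrophils and red blood cells, medians of 0.15, 0.14, 0.16 and 0.19 stood beside a test direction of lower. Camera tests a list against the other genes, so its direction need not follow the list median, and the cause was not tested.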
